A study of Mus musculus with 24 samples.

How the data were processed

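Total RNA of mouse skeletal muscle was measured in 24 samples, 8 in each of the groups STD_Cont, HFD_Cont and HFD_O3. Per the labels' protocols, RNA was isolated with Trizol and 200 ng was labelled with Cy3 for one-colour Agilent arrays. The arrays lie on 3 slides of 8, and each slide carried 2 or 3 arrays of each group. Array rows within the slides were not balanced over the groups. On slide 2 all HFD_Cont arrays lay in row 1 and all STD_Cont arrays in row 2. Row 2 of slide 1 held no STD_Cont array. Per the file headers, the scanner images were read with Agilent Feature Extraction 10.10.1.1, and probe coordinates are on mm9. The deposited scanner files hold spot intensity, as raw mean and median pixel values and as a processed intensity that the software had background-subtracted and detrended, not normalized between arrays. The deposited value table of the authors is in log2 units, and the submitters' processing notes name limma for it without a version. Tested on the values, that table of 30124 probes tracked the log2 median spot signal (lowest correlation 0.9996 over 24 columns), with near-identical quantiles in each column and no background subtraction, and 24 of 24 columns matched their own array best. Its probe filter, the muscle, the sex and age of the mice and the collection hour are not given in the sources used here.

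From the scanner files, flagged spots were left out, spots of a probe were averaged, and the log2 processed intensity was scaled by subtracting each array's 75th percentile over non-control probes. Of 56605 probes, the 29245 that the software marked well above background on at least 6 of the 8 arrays of at least 1 group were kept. The probe with the highest mean stood for each gene name, which gave 19937 names, 6303 of them with more than 1 kept probe. Symbols came from the RefSeq table for 32989 probes whose accession matched, and from the array design otherwise. Between 52 and 60.7% of an array's spots were well above background, 0 spots were saturated, and the 75th percentile signal ranged from 234 to 430.

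Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 24 arrays with no block, with Benjamini-Hochberg adjustment over all names and a threshold of 0.05. Changes are on the log2 scale with the moderated standard error, and group values with their SD. The 33 lists with at least 5 measured genes, of 34 written, were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists. Beside it stand camera with an estimated correlation, the directional test of fry, which does not compare a list with other genes, and an exact permutation of list means between the 2 groups (12870 arrangements). The comparisons, lists, filters, naming rule and most alternatives were fixed before the data were examined. Named were the 12 largest rises and falls past the threshold with a plain symbol, up to 4 members of each list past the threshold over all genes or over the list alone (otherwise up to 2 as values), and, where fewer than 5 genes passed, the 5 smallest p values in each direction. The text gives a selection of these.

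The pipeline was tested on simulated data. With changes of log2 0.5 and 1 added to 100 genes each, 71 and 94% were recovered for HFD_Cont against STD_Cont, with 14 of 19737 unchanged genes called, 71 and 92% with 9 for HFD_O3 against HFD_Cont, and 65 and 94% with 9 for HFD_O3 against STD_Cont. Noise in these data was drawn independently for each gene, with no slide, row or outlying array. The rates therefore need not hold for the real arrays, whose genes vary together. Comparisons that share a group are correlated by construction, so their correlation across genes was set against 100 simulations of unchanged groups and against splits of the shared group into sets of 4 arrays.

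The other settings fixed beforehand were normexp background correction (offset 50), quantile, cyclic loess and median scaling, the deposited table, no filter or a filter on every array, the mean of a gene's probes or every probe, slide as a fixed or random block or each slide alone, the replicate number as a block, only the 2 groups compared, trend and robust variance, array weights, and each array left out in turn. Added after seeing the data were slide and array row as a block, removal of HFD_O3 arrays 1 and 7, removal of 6 arrays with a white adipocyte score over 0.5, that score as a covariate, and the exact permutation of list means. HFD_O3 1 had the lowest score on the second principal component (−38.1), and HFD_O3 7 the highest on the first (27.86), near STD_Cont 3 (25.31). STD_Cont 4 (−30.11 on the second) and HFD_Cont 4 (−26.51 on the third) also lay far out and were not removed with them. Of the 6 adipocyte-rich arrays, HFD_Cont 4 and 5 and HFD_O3 4 and 5 were all of row 1 on slide 2. No sample was left out of the reported values. Files were read with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.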

Results

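Gene expression in mouse skeletal muscle was measured on one-colour oligonucleotide arrays, with 3 groups of 8 mice and 1 array per sample. STD_Cont mice received the low fat control diet and HFD_Cont mice the high fat diet, both in the control lineage. HFD_O3 mice received the high fat diet in the omega-3 lineage. Which muscle was taken, how long the diets lasted, the hour of collection and what sets the omega-3 lineage apart are not given in the sources used here. Spots well above background made up 55.7% ± 2.17 (SD, n = 8) of an HFD_Cont array, 55.3% ± 2.89 of an HFD_O3 array and 55.9% ± 2.78 of an STD_Cont array. The number of arrays, 8 per group, limits the precision of each value below. After the filter on dim probes, 19937 gene names were tested, of which 13670 had a plain gene symbol. The Y-linked gene Eif2s3y was well above background on 24 of 24 arrays and Xist on 0 of 24. The first principal component held 13.2% of the variance, and the mean score was −13.5 ± 7.02 (SD, n = 8) in HFD_Cont, 1.01 ± 16.2 in HFD_O3 and 12.5 ± 9.65 in STD_Cont.

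The comparison of HFD_Cont with STD_Cont asked what the high fat diet changed in muscle of the control lineage. Genes of muscle atrophy and proteolysis fell: 10 of the 31 measured members fell, 0 rose and 21 did not pass the test. Among them Trim63, a ubiquitin ligase that marks sarcomere proteins for breakdown, fell by 1.23 ± 0.25 on the log2 scale (SE, n = 8 per group, adjusted p = 0.0157). Cdkn1a, a cell cycle inhibitor, fell by 1.28 ± 0.27, and Mt1, a metallothionein gene, fell by 1.11 ± 0.23. Depp1, a fasting-induced target of FOXO factors, had the largest fall of any named gene, with a log2 change of −3.14 ± 0.63 (adjusted p = 0.0143, lower in 8 of 8 HFD_Cont arrays than the STD_Cont median). Its probe lies on chromosome 6 of mm9 from 116602564 to 116602623, and its log2 level relative to the array's scaling value was 0.91 ± 0.66 (SD, n = 8) in HFD_Cont and 4.05 ± 1.45 in STD_Cont. Fkbp5, a co-chaperone of steroid receptors that glucocorticoids induce, fell by 1.41 ± 0.32 (SE, adjusted p = 0.0215), the transcription factor gene Cebpd fell by 1.51 ± 0.41 (a call kept in 7 of the 24 fits that left out 1 array), and Hif3a fell by 1.39 ± 0.19 (adjusted p = 0.00151).

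As a list, the atrophy and proteolysis genes were lower in HFD_Cont with a mean log2 change of −0.37 and a median of −0.25 (camera adjusted p = 5e-11). The call was lost at adjusted p = 0.811 with an estimated correlation, while fry gave an adjusted p of 0.0457 and an exact two-sided permutation of the list mean an adjusted p of 0.00513. Adjusted over the list alone, 16 members fell and 0 rose. The unadjusted permutation p of 0.000155 was the smallest that the 12870 arrangements can give. The mean change was −0.38 with slide as a block, and −0.36, −0.39 and −0.38 within the 3 slides that carried the arrays. The exact permutation was added after the data had been seen.

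Among genes of the extracellular matrix, Serpinh1, the collagen-specific chaperone, rose by 0.65 ± 0.09 (SE, n = 8 per group, adjusted p = 0.00151), Col6a3 by 0.57 ± 0.14 and Col4a2 by 0.29 ± 0.08. The calls of Serpinh1, Col6a3 and Col4a2 were kept in 24, 16 and 6 of the 24 fits that left out 1 array. These were 3 of the 42 measured members of the collagen and extracellular matrix list, 0 fell and 39 did not pass, and adjusted over the list alone 8 rose. The list had a mean change of 0.21 and a camera adjusted p of 3.59e-06, against an adjusted p of 0.995 with an estimated correlation and 0.242 by fry. By the exact permutation of list means its adjusted p was 0.0385. Slide as a block gave a mean of 0.23, and the values within slides were 0.33, 0.32 and 0.07. White adipocyte markers had a mean change of 0.38 in the same comparison (camera adjusted p = 0.441), with −0.58, 1.36 and 0.40 within the slides. With the white adipocyte score as a covariate, added after the data had been seen, the collagen list stood at 0.18 and the atrophy list at −0.36. Without the 6 arrays whose adipocyte score was over 0.5, the collagen list stood at 0.11 and the atrophy list at −0.34.

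**Figure D1:**
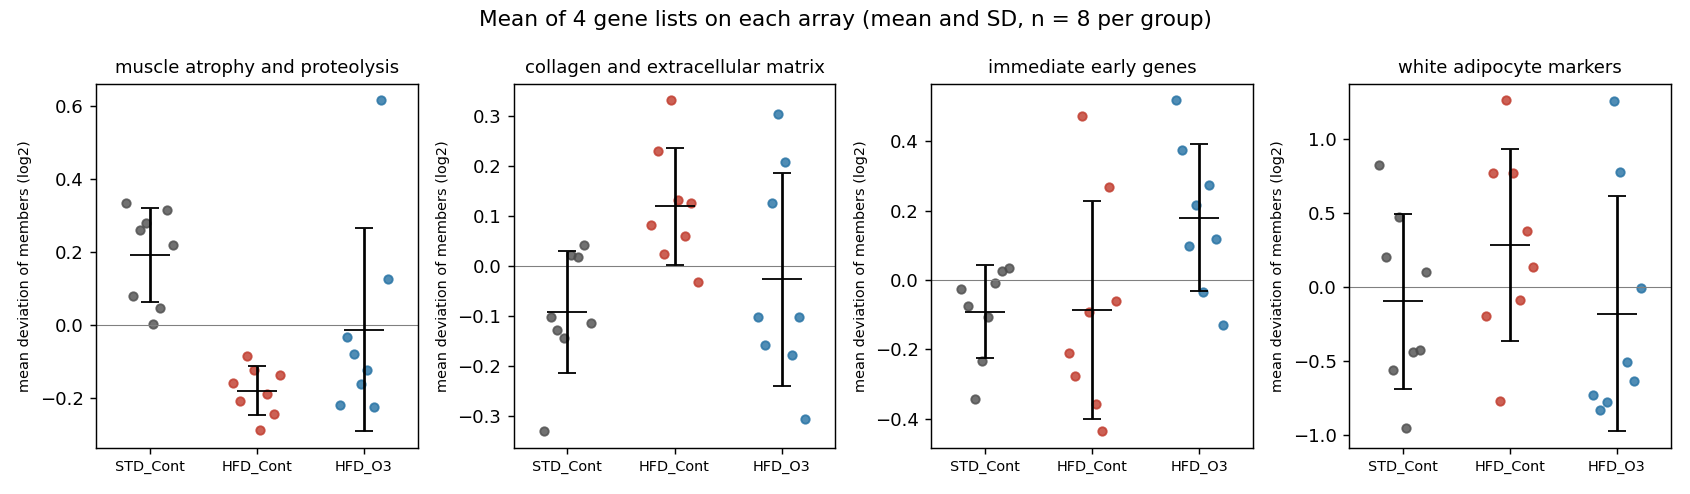
Mean log2 deviation of a list's measured genes from their mean over all arrays, per array (points) with the group mean and SD (n = 8 per group), for the atrophy and proteolysis, collagen and extracellular matrix, immediate early and white adipocyte lists. White adipocyte scores ran from −0.77 to 1.26 in HFD_Cont and from −0.95 to 0.82 in STD_Cont.

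Among genes of fat oxidation, Pdk4, which restrains pyruvate entry into mitochondrial oxidation, fell by 0.54 ± 0.10 (SE, n = 8 per group, adjusted p = 0.0103). The mitochondrial carrier Ucp3 fell by 0.68 ± 0.16 and the peroxisomal enzyme gene Ehhadh fell by 0.84 ± 0.21, whereas Decr1, needed to oxidise unsaturated fatty acids, rose by 0.27 ± 0.07. The calls of Ucp3, Ehhadh and Decr1 were kept in 22, 17 and 10 of the 24 fits that left out 1 array. That made 1 of 40 measured list members higher and 3 lower, with 3 higher and 5 lower adjusted over the list alone. The list itself did not pass (camera adjusted p = 0.976), with a median of 0.04, a mean of −0.07 and a downward test. Clock genes moved in opposite directions. Arntl, the activator of the clock, fell by 0.49 ± 0.11, and the clock-controlled genes Dbp, Nr1d2 and Ciart rose by 0.80 ± 0.21, 0.28 ± 0.07 and 1.61 ± 0.41, calls kept in 12, 19 and 14 of those 24 fits. Of 19 clock genes measured, 3 rose and 1 fell, or 7 and 5 adjusted over the list alone, and the list's camera adjusted p was 0.441.

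Chemokine genes also went both ways. Ccl2, which attracts monocytes, rose by 1.62 ± 0.41 (SE, n = 8 per group, adjusted p = 0.0307, a call kept in 17 of the 24 fits that left out 1 array) and Cxcl12 by 0.49 ± 0.11, and Cxcl13, which attracts B cells, fell by 2.18 ± 0.48. Cxcl13 was well above background on 1 of 8 HFD_Cont arrays and on 8 of 8 STD_Cont arrays, so the size of its fall rests on dim spots. The inflammatory list had 3 members higher and 3 lower of 28, the same counts adjusted over the list alone, and a camera adjusted p of 0.989. Ccnd1, the gene of cyclin D1, rose by 1.11 ± 0.21 (adjusted p = 0.0103), and Nmrk2, a kinase that feeds the synthesis of NAD, by 1.65 ± 0.44 (adjusted p = 0.041, a call kept in 12 of the 24 fits that left out 1 array). Tpx2, which assembles the mitotic spindle, rose by 1.04 ± 0.22, and Prnd by 1.69 ± 0.28 from a level above background on 3 of 8 STD_Cont arrays. In the list of endoplasmic reticulum stress Chac1 fell by 0.94 ± 0.23 and Ppp1r15a fell by 0.55 ± 0.14, whereas Creld2 rose by 0.24 ± 0.06, calls kept in 18, 14 and 15 of those 24 fits. That list had 1 member higher and 3 lower of 32 (1 and 4 adjusted over the list alone) and did not pass, at a camera adjusted p of 0.487. The oxidative stress list was lower, with 1 member lower of 29, Hmox1, the haem-degrading enzyme gene, which fell by 0.72 ± 0.13, and 4 lower adjusted over the list alone, with a mean of −0.11 and a camera adjusted p of 0.0462. It was not called at an adjusted p of 0.995 with an estimated correlation, and its means were −0.10 with slide as a block and −0.16, −0.05 and −0.11 within slides. Leaving out 1 array ended its call in 11 of 24 fits, and that of the tendon list below in 6. Tendon markers were called higher at a camera adjusted p of 0.0325 and a mean of 0.27, although the 1 of 13 members past the threshold, Angptl7, fell by 0.93 ± 0.22 (a call kept in 18 of those 24 fits). Their adjusted p was 0.995 with an estimated correlation, and the means were 0.33 with slide as a block and 0.37, 0.58 and 0.11 within slides.

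**Figure D2:**
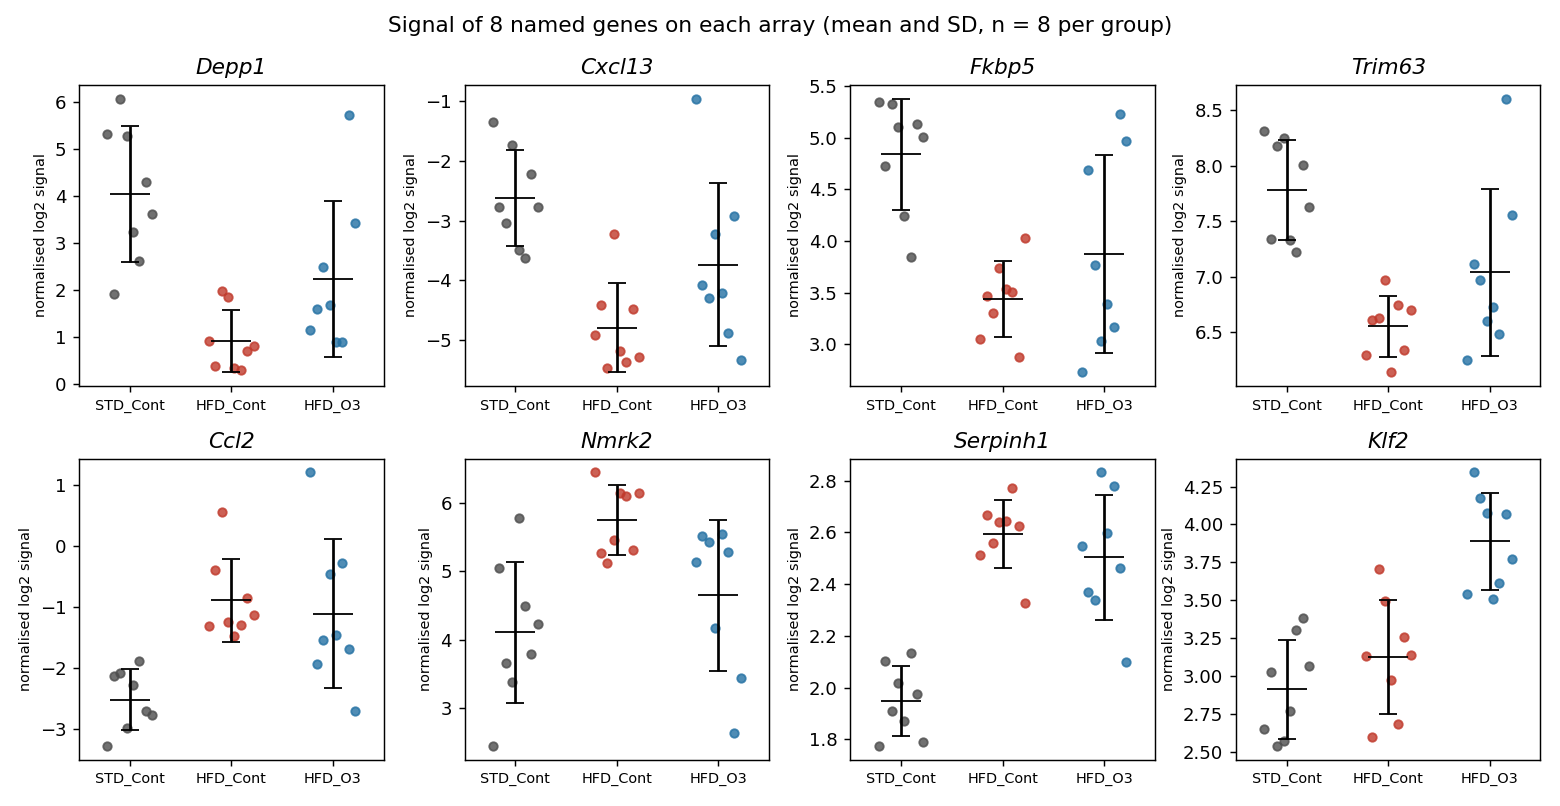
Log2 signal relative to each array's scaling value for 8 named genes, per array (points) with the group mean and SD (n = 8 per group). Depp1 averaged 4.05 in STD_Cont and 0.91 in HFD_Cont.

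By limma with Benjamini-Hochberg adjustment, 581 of 19937 gene names differed between HFD_Cont and STD_Cont at an adjusted p under 0.05, 286 higher and 295 lower. The median absolute log2 change among them was 0.416, and 38 exceeded 1. At an unadjusted p under 0.05 there were 3300, where chance gives a mean of 997 with a spread that was not computed. Of 33 gene lists camera called 4, 2 higher and 2 lower, against 0 with an estimated correlation, 1 by fry and 2 by the exact permutation. The count of genes moved most with the arrays used, to 0 without the 6 adipocyte-rich arrays (50 random removals of as many arrays per group gave a median of 13.5, from 0 to 418), to 0 within each slide, to 177 with median scaling, to 135 with no filter and to 73 with slide and array row as a block. It ran from 182 without STD_Cont 1 to 977 without HFD_O3 7 when 1 array was left out, and was 1238 without HFD_O3 arrays 1 and 7, 1166 with only these 2 groups in the fit and 1168 with array weights. The adipocyte-rich arrays included all of row 1 on slide 2, so adipocyte content and array position cannot be told apart there. The random removals did not copy that position. Group and array row were in part confounded, so the fall with the row block has no single reading.

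The comparison of HFD_O3 with HFD_Cont asked what the omega-3 lineage changed under the high fat diet. Immediate early genes, which answer to stimuli within minutes, stood higher as a list in HFD_O3, with a mean log2 difference of 0.27 over 27 measured members and a median of 0.30 (camera adjusted p = 6.87e-08, but adjusted p = 0.462 with an estimated correlation). The exact permutation of list means did not call this list either (adjusted p = 0.562, unadjusted p = 0.0687). None of the members passed over all genes, and 4 were higher adjusted over the list alone. These were the transcription factor genes Klf2, with 0.77 ± 0.16 (SE, n = 8 per group, adjusted p over all genes = 0.341), Klf4 with 0.56 ± 0.14, Fosl2 with 0.38 ± 0.09 and Klf6 with 0.48 ± 0.12. The list's means were 0.28 with slide as a block and 0.34, 0.38 and 0.07 within slides. Heat shock protein genes had a mean of 0.15 over 22 members (camera adjusted p = 7.01e-06), and adjusted over the list alone only Dnajb1, a co-chaperone gene, passed, with 0.51 ± 0.09. That list's adjusted p was 0.462 with an estimated correlation and 0.562 by the exact permutation. Its means were 0.17 with slide as a block and 0.08, 0.33 and 0.08 within slides.

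Of the 4 lists called with the diet, the atrophy, collagen and tendon lists were called with the opposite sign in HFD_O3 against HFD_Cont, and the oxidative stress list was not called (mean 0.01, camera adjusted p = 0.184). Both comparisons hold the HFD_Cont arrays, which by itself favours opposite signs. Atrophy and proteolysis genes had a mean of 0.17 above HFD_Cont (camera adjusted p = 7.63e-07, adjusted p = 0.622 with an estimated correlation), with 0 of 31 members past the threshold, also 0 adjusted over the list alone. Their mean was 0.19 with slide as a block and 0.04, 0.04 and 0.56 within slides, and the mean with all arrays went from 0.167 to 0.077 without HFD_O3 7. Collagen and extracellular matrix genes had a mean of −0.145 (camera adjusted p = 0.000363, adjusted p = 0.761 with an estimated correlation), −0.16 with slide as a block and −0.16, −0.12 and −0.26 within slides, with 0 of 42 members past the threshold over all genes or adjusted over the list alone. Fat oxidation genes, not called with the diet, had a mean of 0.10 (camera adjusted p = 0.000208, adjusted p = 0.761 with an estimated correlation) and 0 of 40 members past the threshold, 0.11 with slide as a block but −0.10, 0.25 and 0.22 within slides. Tendon markers had a mean of −0.26 (adjusted p = 0.00965, or 0.761 with an estimated correlation), −0.30 with slide as a block and −0.19, −0.36 and −0.44 within slides. Fibroblast markers had a mean of −0.11 (adjusted p = 0.0238, or 0.761 with an estimated correlation), −0.12 with slide as a block and −0.14, −0.13 and −0.12 within slides, and −0.07 without HFD_O3 1. Endothelial markers had a mean of 0.06 (adjusted p = 0.00205, or 0.622 with an estimated correlation), 0.06 with slide as a block and 0.07, 0.08 and 0.01 within slides. Interferon response genes had a mean of 0.08 (adjusted p = 0.0245, or 0.761 with an estimated correlation), 0.07 with slide as a block and 0.16, −0.11 and 0.13 within slides, and it went to 0.033 without HFD_Cont 2, 0.051 without HFD_Cont 8, 0.05 without HFD_O3 7 and 0.117 without HFD_Cont 4. Erythroid and Schwann cell markers had means of −0.14 and −0.25 (adjusted p = 0.036 for both, or 0.761 with an estimated correlation), −0.14 and −0.24 with slide as a block. Within slides the erythroid means were −0.18, 0.02 and −0.24, and the Schwann cell means 0.21, −0.28 and −0.76. Without HFD_Cont 3 the erythroid mean was −0.088, and without HFD_Cont 8 the Schwann cell mean was −0.113. Of the 24 fits that each left out 1 array, the call was lost in 7 for the interferon and Schwann cell lists, in 6 for the fibroblast and erythroid lists and in 2 for the tendon list. White adipocyte markers had a mean of −0.46 (adjusted p = 0.0836).

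By limma, 0 of 19937 gene names differed between HFD_O3 and HFD_Cont, with a smallest adjusted p of 0.188. There were 1412 names at an unadjusted p under 0.05, where chance gives a mean of 997. Genes vary together, so the count by chance can lie well away from that mean, and its spread was not computed. Among the smallest p values were those of Dnajb1 and Klf2, of Epha2, an ephrin receptor gene, with 0.51 ± 0.11 (SE, n = 8 per group), of Hdc, the histamine-forming enzyme gene, with 0.73 ± 0.17, and of Nod2 with 0.37 ± 0.08. Lower values were those of Cacna2d4, a calcium channel subunit gene, with −1.11 ± 0.25, Mfap3l with −0.58 ± 0.12, Rap1gap2 with −0.47 ± 0.11, Aldoc with −0.41 ± 0.09 and Fbxw7 with −0.21 ± 0.05. Per1, a clock gene, had 0.81 ± 0.20 and passed adjusted over the list alone, but its 2 probes pointed in opposite directions. Camera called 11 of 33 lists, 6 higher and 5 lower, and neither an estimated correlation, fry nor the exact permutation (smallest adjusted p = 0.562) called any. In other splits of these arrays into groups of 8, camera called a median of 8 lists. The count of genes was also 0 under every other normalization, filter and block tried, and 1, Epha2 at an adjusted p of 0.0457, without HFD_Cont array 3.

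The comparison of HFD_O3 with STD_Cont took diet and lineage together. Of 27 immediate early genes measured 4 rose, 0 fell and 23 did not pass: Klf2 by 0.98 ± 0.16 (SE, n = 8 per group, adjusted p = 0.0071), Klf4 by 0.84 ± 0.14, Nr4a1 by 0.66 ± 0.13 and Fosl2 by 0.43 ± 0.09 (a call kept in 18 of the 24 fits that left out 1 array). Adjusted over the list alone 7 rose and 1 fell. The list's mean was 0.27 (camera adjusted p = 3.33e-05, adjusted p = 0.67 with an estimated correlation), 0.26 with slide as a block and 0.38, 0.38 and −0.02 within slides. Slc25a25, a mitochondrial carrier of ATP and magnesium, rose by 1.72 ± 0.30 (adjusted p = 0.00741), Apold1, an endothelial early response gene, by 1.21 ± 0.22, Id1 by 0.99 ± 0.18 and Avil, an actin-binding protein gene, by 0.93 ± 0.12 (adjusted p = 0.000625). The probe of Slc25a25 was higher on 8 of 8 HFD_O3 arrays than the STD_Cont median, as was that of Avil. Slc2a4, the insulin-responsive glucose transporter gene, fell by 0.215 ± 0.05 (adjusted p = 0.0489, a call kept in 3 of the 24 fits that left out 1 array), Cacna2d4 fell by 1.27 ± 0.25, and Cd27, a lymphocyte receptor gene above background on 4 of 8 HFD_O3 arrays, fell by 1.46 ± 0.26.

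Heat shock genes had 2 of 22 members higher, Dnajb1 by 0.57 ± 0.09 (SE, n = 8 per group, adjusted p = 0.00635) and Dnaja1 by 0.33 ± 0.07, also 2 adjusted over the list alone. The list's mean was 0.15 (camera adjusted p = 0.00208, adjusted p = 0.67 with an estimated correlation), 0.15 with slide as a block and 0.23, 0.26 and −0.04 within slides. Serpinh1 rose by 0.56 ± 0.09 (adjusted p = 0.00635) as the 1 called member of 42 in the matrix list, which had 2 higher and 2 lower adjusted over the list alone. The matrix list's mean was 0.07 (adjusted p = 0.0339, or 0.67 with an estimated correlation), 0.07 with slide as a block and 0.17, 0.20 and −0.19 within slides. It went to 0.019 without HFD_O3 4, 0.033 without HFD_O3 5, 0.032 without STD_Cont 1 and 0.106 without HFD_O3 8, and the call was lost in 6 of 24 fits that left out 1 array. Atrophy and proteolysis genes had 0 of 31 members past the threshold and 3 lower adjusted over the list alone, with a mean of −0.205 (camera adjusted p = 0.00104, or 0.67 with an estimated correlation), −0.19 with slide as a block and −0.32, −0.35 and 0.18 within slides. Erythroid markers had a mean of −0.27 (adjusted p = 0.000512, or 0.67 with an estimated correlation), 6 of 9 members lower adjusted over the list alone, −0.27 with slide as a block and −0.59, −0.07 and −0.25 within slides. Schwann cell markers had a mean of −0.42 (adjusted p = 0.00231, or 0.67 with an estimated correlation), −0.40 with slide as a block and −0.36, −0.36 and −0.61 within slides. Endothelial markers had a mean of 0.09 (adjusted p = 0.00529, or 0.67 with an estimated correlation), with 0 of 23 members past the threshold and 3 higher adjusted over the list alone, 0.09 with slide as a block and 0.10, 0.14 and 0.01 within slides. Fat oxidation genes had a mean of 0.03 (adjusted p = 0.00618, or 0.67 with an estimated correlation), 4 higher and 1 lower adjusted over the list alone, 0.03 with slide as a block and 0.03, 0.06 and 0.05 within slides. Without 1 array it was 0.054 (HFD_O3 1 or STD_Cont 3), 0.046 (STD_Cont 6), 0.01 (STD_Cont 2 or HFD_O3 4), 0.001 (STD_Cont 5) or −0.002 (HFD_O3 7), and the call was lost in 3 of 24 fits. Interferon response and antigen presentation genes had means of 0.07 and 0.10 (adjusted p = 0.00956 and 0.0178, or 0.67 with an estimated correlation), 0.08 and 0.10 with slide as a block. Within slides they were 0.14, −0.01 and 0.12 for the first and 0.12, 0.05 and 0.15 for the other. The antigen presentation mean over all arrays depended most on HFD_O3 4, without which it was 0.004, and it was 0.065 without STD_Cont 7. Without that array the list's camera adjusted p was 0.713. Slides 1 and 3, which do not hold HFD_O3 4, gave 0.12 ± 0.07 and 0.15 ± 0.18 (SE), too imprecise to show that the rise holds without it. The interferon mean was 0.046 without HFD_O3 7 and 0.048 without STD_Cont 2. Of 24 such fits, the call was lost in 5 for antigen presentation and in 3 for interferon response. Over all genes, 0 members of the erythroid, Schwann cell, fat oxidation, interferon response and antigen presentation lists passed the threshold.

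By limma, 119 gene names differed between HFD_O3 and STD_Cont, 81 higher and 38 lower, with 2236 at an unadjusted p under 0.05. With median scaling these were 49 higher and 13 lower. Camera called 10 of 33 lists, 7 higher and 3 lower, against 0 with an estimated correlation, 0 by fry and 0 by the exact permutation. The count was 1 without the 6 adipocyte-rich arrays (50 random removals of as many arrays per group gave a median of 32, from 1 to 320), 36 with only these 2 groups in the fit, 46 with no filter, 47 with slide and array row as a block and 0 within each slide, and leaving out 1 array gave from 68 without STD_Cont 3 or HFD_O3 6 to 343 without HFD_O3 7. Here too the adipocyte-rich arrays included all of row 1 on slide 2, which held no STD_Cont array.

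The high fat changes of both lineages were set side by side, against the same STD_Cont arrays. Of genes called higher in either comparison 43 were shared, where independent calls would share 1.16, and of genes called lower 24 were shared, against 0.562. The shared STD_Cont arrays break that independence. In 100 simulations of unchanged groups with the same shared arrays limma called 0 genes in both comparisons, which does not cover groups with many called genes. Hif3a was among the shared falls, with −1.39 ± 0.19 in HFD_Cont and −0.94 ± 0.19 in HFD_O3 (SE, n = 8 per group), and Serpinh1 and Nr4a1 among the shared rises. All 581 genes called with the diet had the same sign in HFD_O3 minus STD_Cont, and 528 had a smaller change there, with a median ratio of 0.628. Since these genes were chosen for their change in HFD_Cont, a smaller change in another group follows in part from the choice. Genes called with 4 of the HFD_Cont arrays, in the 3 of 70 splits that called at least 20, had a median change of 0.314 in the other HFD_Cont arrays and 0.316 in HFD_O3, and the change was smaller in HFD_O3 in 2 of these 3 splits. Across all 19937 names the changes of HFD_Cont and HFD_O3 correlated with r = 0.659, where unchanged groups sharing arrays gave a mean of 0.501 and a range from 0.116 to 0.795. The diet change and the lineage difference correlated with r = −0.539, against a simulated mean of −0.479 and a range from −0.739 to −0.159. Genes are not independent replicates, and both values lay inside what shared arrays alone give. With the shared group split into separate sets of 4 arrays, r averaged 0.302 (from 0.094 to 0.472) and −0.204 (from −0.325 to −0.082) over 70 splits. Sets without shared arrays favour neither sign, and all 70 splits had the same sign as r with all arrays, but the splits reuse the same arrays and are not separate tests.

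**Figure D3:**
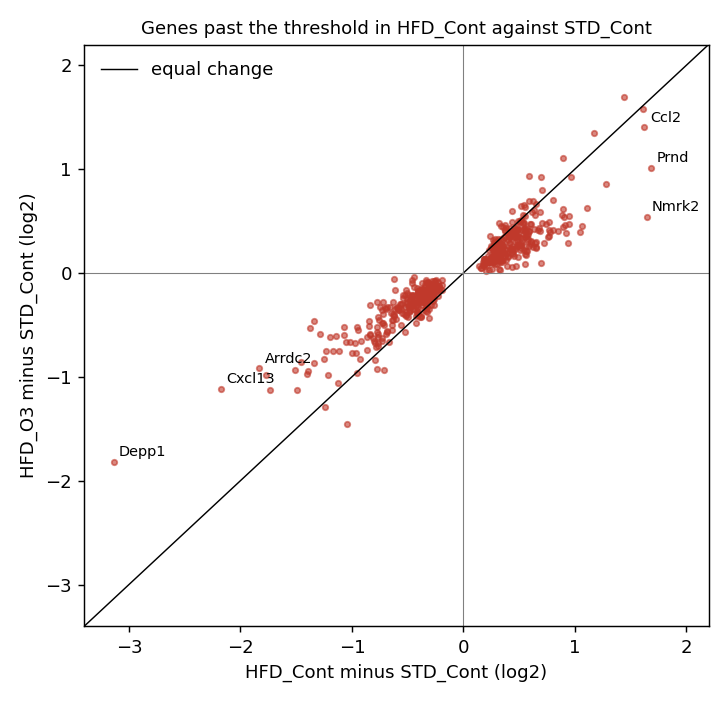
Log2 change against STD_Cont in HFD_Cont (horizontal) and in HFD_O3 (vertical) for the 581 genes called in HFD_Cont against STD_Cont, 1 point per gene (means of 8 arrays per group). All 581 points have the same sign on both axes, and both axes use the same STD_Cont arrays.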

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

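The counts of other splits were planned, whereas the tests of slide, clock phase, glucocorticoid-raised genes, 1 array, fibroblast and tendon RNA were chosen only after the result was seen. For the diet in the control lineage, 1 of 100 splits of the 16 arrays, the real one, gave as many genes (581, highest other 1). That is the smallest share 100 splits can give, which argues against chance for the gene count without excluding it. The splits took no account of array row. For its lists 86 of 100 splits gave as many as the real 4 (median of the others 8, highest 15), so chance is not excluded for that count. For HFD_O3 against HFD_Cont, the real gene count was 0 by limma (1412 at an unadjusted p under 0.05), so all 100 of 100 splits had to give at least as many and nothing follows from it (highest other 23). Its lists were matched by 37 of 100 splits (real 11, median of the others 8, highest 20), and chance is not excluded for that count. For HFD_O3 against STD_Cont, 1 of 100 splits gave as many genes as the real 119 (highest other 56), which again argues against chance without excluding it. As many lists as the real 10 came from 31 splits (median of the others 8, highest 17), so chance is not excluded for that count.

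The lower atrophy and proteolysis list in HFD_Cont than in STD_Cont was weighed against slide, another clock phase at collection and lower glucocorticoid-type signalling. Slide as the whole cause is argued against by the layout and by the same sign in all 3 slides. Each slide carried 2 or 3 arrays of each group, so slide as a block could move the difference little (−0.377 ± 0.088, SE). On slide 2 HFD_Cont and STD_Cont lay in different array rows, and array row was not weighed here. Clock output genes less activator genes differed by 0.893 ± 0.185, which restates the called clock genes, and by 0.543 ± 0.13 without those 4 (exact two-sided permutation p = 0.00124, 5 output genes and 1 activator gene of the same circuit), so another clock phase at collection and a change of the clock with the diet both stay open, with no collection hour given. Other glucocorticoid-raised genes, 15 not on the list, had a mean difference of −0.34 ± 0.072 (exact two-sided permutation p = 0.0014, 13 of 15 lower, 6 past the limma threshold, among them Glul with −1.14 and Klf9 with −0.49). The test was chosen after these calls had been seen. It was not repeated without the 6 called genes, so its p in part restates them. Lower glucocorticoid-type signalling stays open as well. The diet that the design names stays open, untested apart from these.

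The higher immediate early list in HFD_O3 than in HFD_Cont was weighed against 1 array and slide. A single array as the whole cause is argued against, since the lowest difference without 1 array was 0.216 (without HFD_Cont 6) against 0.266 with all. Slide as the whole cause is argued against only by the layout, with 2 or 3 arrays of each group on each slide. Slide as a block could therefore move the difference little (0.278 ± 0.114, SE, from a fit of all 3 groups). Without a block the difference was 0.266 ± 0.134 from the arrays of these 2 groups, so it was itself uncertain. The third slide alone gave 0.07 ± 0.278. The exact permutation of list means did not pass the threshold (adjusted p = 0.562). The lineage that the design names stays open as a hypothesis, and handling at dissection was not tested.

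The higher collagen list in HFD_Cont than in STD_Cont was weighed against slide and a larger share of fibroblast or of tendon RNA. Slide as the whole cause is argued against by the layout and by the same sign in all 3 slides. Each slide carried 2 or 3 arrays of each group, so slide as a block could move the difference little (0.227 ± 0.076, SE). The third slide alone gave 0.07 ± 0.066. A larger share of fibroblast RNA that lifts both lists alike is argued against. The collagen list exceeded the fibroblast list by 0.163 ± 0.041, and the fibroblast list itself stood at 0.048 ± 0.052. A share that lifts collagen genes more than the marker list was not tested and stays open. More tendon RNA stays open, since the 11 tendon markers not on the collagen list stood at 0.267 ± 0.155, which is 0.055 ± 0.123 above the collagen list. That rise is itself uncertain, as the full tendon list did not pass the exact permutation of list means (adjusted p = 0.432). Its only called member, Angptl7, fell (−0.93). A larger share of adipose RNA and array row were not weighed here. White adipocyte markers stood at 0.38 ± 0.311 (SE), and the collagen mean was smaller without the adipocyte-rich arrays. On slide 2 HFD_Cont and STD_Cont lay in different array rows. The diet that the design names stays open as well.

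In 213 group values tested for a single array set apart from the other 7, 12 stood apart, where chance flags about 1 in 20 groups, or 11 here. The values are deviations from the median of the other arrays of the group. Sybu was −2.14 in STD_Cont 3 and 0.704 in HFD_Cont 4. Mex3a was −1.42 in STD_Cont 1, and Cxcl13 was 1.96 in HFD_Cont 4. In HFD_O3 7, Arrdc2 was 2.93 and the atrophy list 0.74. Dnajb1 was 0.235 and Kcnab1 −0.872 in HFD_Cont 3. Fosl2 was −0.335 in HFD_Cont 5, Slc25a25 1.78 in STD_Cont 5 and Neto2 1.01 in STD_Cont 2. The antigen presentation list was 0.816 in HFD_O3 4.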

How the results depend on the processing

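The alternatives with slide and array row, the arrays left out as sets, the adipocyte covariate and the exact permutation were chosen after seeing the data, and the rest were planned. Where a value moved and nothing else is said, the cause was not tested. Signal over background limits dim genes such as Cxcl13 and Mex3a. Genes dim on some arrays have no value under the filter on every array.

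Genes changed in HFD_Cont against STD_Cont, 581, came to 177 with median scaling, 135 with no filter, 1166 with only the 2 groups compared, 1168 with array weights, 73 with slide and array row as a block, 1238 without HFD_O3 arrays 1 and 7 and 0 without the 6 adipocyte-rich arrays. In HFD_O3 against STD_Cont the 119 came to 62, 46 and 36 under the first 3 of these, 47 with slide and row and 1 without the adipocyte-rich arrays. Within slides 1, 2 and 3 both counts were 0, with 2 or 3 arrays per group. The other alternatives gave from 413 to 711 for the diet (with every probe on its own 692 genes, from 781 probes) and from 84 to 174 for HFD_O3 against STD_Cont, and by limma 0 in HFD_O3 against HFD_Cont throughout (1412 at an unadjusted p under 0.05 with all arrays).

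Leaving out 1 array gave 182 (STD_Cont 1) to 977 (HFD_O3 7) genes for the diet, and the other arrays that moved it by over 1.5 times were STD_Cont 3 (263), 4 (319) and 7 (335), HFD_Cont 1 (365), 2 (319), 4 (375), 5 (274), 6 (385) and 7 (381). For HFD_O3 against HFD_Cont it gave 0 to 1 (HFD_Cont 3). For HFD_O3 against STD_Cont it gave 68 (STD_Cont 3 or HFD_O3 6) to 343 (HFD_O3 7), with STD_Cont 1 (69), 2 (71) and 8 (73) and HFD_O3 1 (74), 4 (70) and 8 (200). Lists ranged from 2 to 6 of 4 called, with 2 without STD_Cont 1, 2 or 8 or HFD_Cont 5 or 7, from 8 to 13 of 11 and from 7 to 11 of 10.

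Lists changed with the diet, 4, came to 2 with quantile normalization or the filter on every array, 7 with no filter, 15 within slide 1, 0 with an estimated correlation, 1 by fry and 2 by exact permutation. The 11 lists of HFD_O3 against HFD_Cont came to 7 within slide 3, without HFD_O3 arrays 1 and 7 or with the adipocyte covariate, and the 10 of HFD_O3 against STD_Cont to 16 within slide 1. Both were 0 with an estimated correlation, by fry and by exact permutation.

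List means that reversed in HFD_O3 against HFD_Cont were −0.102 for fat oxidation and 0.209 for Schwann cell markers within slide 1, and −0.11 for interferon response and 0.017 for erythroid markers within slide 2. In HFD_O3 against STD_Cont they were −0.006 for interferon response within slide 2, and 0.176 for atrophy, −0.044 for heat shock, −0.023 for immediate early and −0.186 for collagen genes within slide 3. Collagen was −0.031 with slide and array row as a block and −0.062 without the adipocyte-rich arrays, antigen presentation −0.005 without those, and fat oxidation −0.002 without HFD_O3 7 (up to 0.054 without HFD_O3 1).

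The correlation of the diet change with HFD_O3 minus STD_Cont, 0.659, was 0.281 within slide 3 and 0.813 on genes called with 4 arrays of the shared group (29 of 70 splits with at least 20 such genes), and from 0.582 to 0.712 without 1 array. That with the lineage difference, −0.539, was −0.37 within slide 1, −0.383 on genes called with 4 such arrays (only 3 of 70 splits), and from −0.592 to −0.444 without 1 array. Genes named and called kept their sign in each alternative (53 for the diet, 31 for HFD_O3 against STD_Cont), and 24 and 16 of them kept the call without any 1 array.

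Nothing in the labels pairs arrays by replicate number. Within each group the number rose in the order of slide and array position, so arrays of the same number mostly shared a slide. Of 24 same-number pairs 6 correlated above 0.1 (from −0.145 to 0.365, median 0.044, against −0.006 for other numbers). Among the 24 arrays, 6 matched their own number best, where chance gives 3 if position is ignored. The number thus follows array position, and these values give no evidence of a pairing of mice beyond it. With the number as a block, which is in part a block on slide and position, the genes came to 628, 0 and 89 and the lists to 3, 11 and 10.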

Other observations

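Genes named for the fate of n-3 and n-6 fatty acids, such as lipoxygenases and epoxide hydrolases, had 22 measured members, and 0 passed the threshold by limma in any comparison, over all genes or adjusted over the list alone. The list's camera adjusted p was 0.881 for HFD_Cont against STD_Cont, 0.281 for HFD_O3 against HFD_Cont and 0.802 for HFD_O3 against STD_Cont. Alox5, the gene of 5-lipoxygenase, had −0.63 ± 0.24 (SE, n = 8 per group) in HFD_O3 against HFD_Cont and did not pass (adjusted p = 0.638). Nuclear-encoded genes of oxidative phosphorylation had 59 measured members and 0 past the threshold by limma in HFD_Cont against STD_Cont, with a median of 0.03 and a camera adjusted p of 0.243. Markers of slow fibres had a mean of −0.26 there (camera adjusted p = 0.441), with Myh7, the slow myosin heavy chain gene, at −0.64 ± 0.66. The slow fibre means were 0.99, −1.30 and −0.79 within slides, so the sign was not the same throughout. Scores of that list ran from −2.674 to 1.075 in HFD_Cont and from −0.494 to 1.262 in STD_Cont. Ptpn1, a phosphatase gene that damps insulin signalling, fell by 0.34 ± 0.07 (adjusted p = 0.0174) as the 1 called member of 30 in the insulin list, whose camera adjusted p was 0.989. Adjusted over the list alone, 3 members of that list rose and 4 fell.

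With the diet in the control lineage, Meox1 rose by 0.57 ± 0.10 (SE, n = 8 per group, adjusted p = 0.00865) as the 1 called member of 19 fibroblast markers, whose camera adjusted p was 0.556. Kdr, the endothelial receptor of VEGF, rose by 0.45 ± 0.10 and Aqp1, a water channel gene, fell by 0.28 ± 0.08 (a call kept in 6 of the 24 fits that left out 1 array) among 23 endothelial and mural markers. Plin4, a lipid droplet coat gene on the white adipocyte list, fell by 0.72 ± 0.15 although that list had a mean of 0.38.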
